A study of Staphylococcus aureus with 6 samples.

How the data were processed

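RNA sequencing libraries of Staphylococcus aureus were compared between flasks grown with an essential oil (EO) and control flasks grown in broth alone (NC), with 3 libraries in each of 2 groups. Per the labels' protocols, 1 colony was grown in 5 mL of broth for 24 h at 37 °C, and 43 µL of that suspension was added to each of 6 flasks of 250 mL. The EO flasks held 43.75 mL of broth and 6.25 mL of an EO working solution, which was 12.5% of the volume, and the NC flasks held 50 mL of broth. Growth lasted 5 h in all flasks, at 37 °C with shaking at 200 rpm, and total RNA was then extracted. The flasks were separate but shared 1 preculture, so p-values measure the spread between flasks of that preculture. What the EO working solution held besides the oil is not given in the sources used here, and the control flasks received no such solution.

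The deposited values are log2(TPM + 1), where TPM is the length-scaled share of transcripts, although they are named TPM. This was read from the values, because 2 to the power of each value, minus 1, summed to 1000000 in every library. Per the submitters' processing notes, which give no role or order, the tools were cutadapt 1.15, HISAT2 2.0.5, HTSeq 0.9.1 and DESeq 1.30.0. The genome build, the annotation, the read length and the use of strand in counting are not given in the sources used here. Whether reads from overlapping, antisense or near-identical genes were told apart is therefore not known. The table held 2745 genes and 0 columns of other samples.

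Gene names came only from a reference table of the assembly ASM1342v1. All 2745 gene IDs matched it, 218 of them with a symbol and 8 more through a synonym, so 226 genes had a name. That table was used for names, gene lengths and neighbouring genes only, and the strain in the flasks is not given in the sources used here.

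The depth was recovered from the values. Multiplied by the coding length minus 3 bases, the TPM values of a library were whole multiples of 1 step, taken as 1 read. Of 11661 values above 0, 99.7% came out whole within 0.001 of a read, and 2739 genes were whole in all 6 libraries. The other 6 genes, whose lengths did not match, were left out of fits on reads. A common factor in all counts of a library would not be seen in this way. For a gene of the median length of 729 nt, 1 read was worth between 4.65 and 8.94 TPM, and 3 reads between 14.0 and 26.8 TPM. Intervals on shares of reads are 95% Wilson intervals and cover counting error only, since reads without molecular identifiers are not independent molecules.

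The main test was limma 3.58.1 in R 4.3.3 with an intensity trend on log2(TPM + 1), over genes with at least 1 TPM in at least 3 of the 6 libraries. It was two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes of this fit are on the log2(TPM + 1) scale, which understates the change of genes low in all libraries and can overstate it where 1 library is at 0, and a second count took those of at least 1 in log2. Gene lists were tested with camera at a preset correlation of 0.01, for lists with at least 3 measured members, and with fry and an estimated correlation as alternatives. The test, the alternatives on pseudocount, filter, scaling, trend, block and replicates, the 35 gene lists and the rule for named genes were fixed before the data were examined. The symbols of 13 lists matched no named gene: the cell wall stress stimulon, autolysins, agr and toxins, secreted proteases and lipases, adhesins and biofilm, capsule, iron acquisition, other metals, sigma B and staphyloxanthin, lysine with threonine and methionine synthesis, multidrug efflux, osmoprotectant transport, and stable RNA. No value is reported for these.

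The rule for named genes took the called genes with a symbol and the largest changes, called members of the lists, and 14 regulators and housekeeping genes in any case. Because the main test called no gene, it named only tpiA, the 1 of those 14 with a symbol. The other genes named below were chosen after the values were seen. They are the 2 members of each tested list with the most reads, and the genes with a name that a fit on reads called. The 2 largest changes in each direction and the 3 most abundant genes were added. List members that passed when adjusted over their list alone are named as well.

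A fit on the recovered reads was added after the data were examined. It weights each value by its precision at the depth of its library, and used limma voom with median-of-ratios scaling for genes with at least 30 reads in total, and total reads as a second scaling. It was first run with the 6 genes of unmatched length kept, and that version is among its alternatives. Further additions were a filter of mean TPM of at least 100 and thinning of all libraries to the 30522 reads of the shallowest, in 20 draws. A second thinning, to 14022 reads outside the 10 most abundant genes, was used for the median fold change only.

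The fits were tested on simulated data, with 5 runs of the EO against NC comparison and 200 changed genes. Depths followed the median-of-ratios factors of the libraries. Unchanged genes had the same mean in both groups, and all genes had 1 common spread. The real difference in the share of abundant genes was thus not simulated. With no changed gene the log2(TPM + 1) fit gave a median log2 fold change of 0.18, against 1.45 in the real data. The values below therefore need not hold for these libraries. The log2(TPM + 1) fit recovered 0% of genes changed 2-fold, 36.4% of those changed 4-fold and 73.4% of those changed 8-fold, over about 2273 to 2289 genes. The fit on reads with median-of-ratios scaling recovered 14.6%, 91.2% and 99.8%, over about 1400 to 1421 genes. These shares are of the changed genes that passed each filter, which for the fit on reads were on average 186.4, 170 and 161.4 of the 200. With no changed gene, both made 0 false calls. With 4-fold and 8-fold changes the log2(TPM + 1) fit made on average 15.2 and 25.6 false calls beside 72.8 and 146.6 true ones, and the fit on reads made 3.8 and 4.4 beside 155 and 161. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.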

Results

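The series asked how an essential oil affects gene expression in the bacterium Staphylococcus aureus. Gene expression was measured in 6 libraries, 3 from flasks with the essential oil (EO) and 3 from control flasks (NC), after 5 h of growth. The deposited table gave 2745 genes. The recovered depth was low and differed between the groups. The NC libraries held 70689, 68355 and 30522 reads on genes, and the EO libraries held 105621, 112361 and 113844. The 3 EO libraries all lay above the 3 NC libraries (two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give). NC replicates 1, 2 and 3 listed 823, 898 and 1320 genes at 0, against 500, 606 and 662 in the EO replicates.

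**Figure D1:**
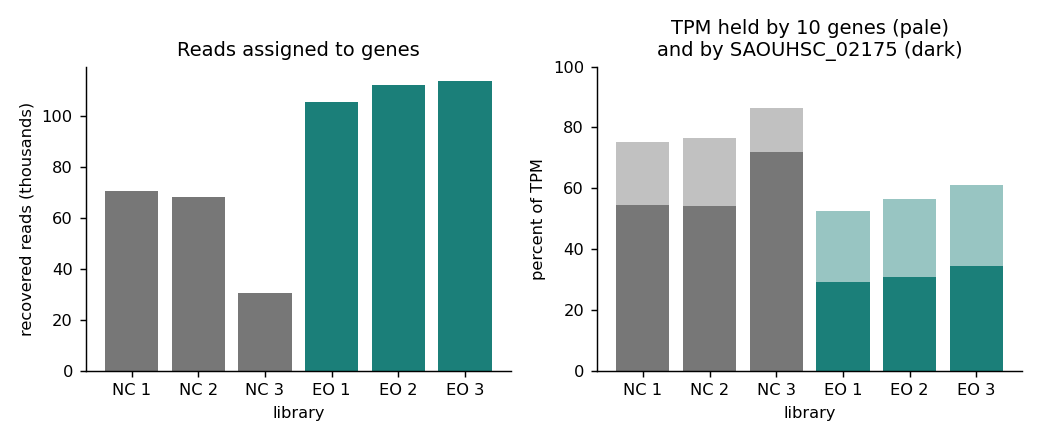
The left bars give recovered reads per library, and the right bars give the percent of TPM held by the 10 most abundant genes (pale) and by SAOUHSC_02175 (dark). Controls are grey and EO libraries green. NC replicate 3 had 30522 reads, the fewest, and 86.5% of its TPM in 10 genes.

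A single short gene dominated the libraries. SAOUHSC_02175, an unnamed gene of 108 nt, held 60.3% ± 10.1 of TPM in NC and 31.5% ± 2.71 in EO (SD, n = 3 each). As a share of reads it held 21.0% (95% Wilson interval 20.7 to 21.3), 21.5% and 38.1% in the NC libraries and 7.09%, 7.97% and 9.39% in the EO libraries. The share was lower in all 3 EO libraries than in any NC library (two-sided exact permutation p = 0.1, the smallest possible). The 10 most abundant genes held 79.3% ± 6.24 of TPM in NC and 56.7% ± 4.31 in EO (SD, n = 3 each). Because TPM sums to a fixed total, a lower share of these genes raises the values of all others. The mean Pearson correlation across genes was 0.68 between NC libraries, 0.79 between EO libraries and 0.70 between the groups, and genes are not independent replicates. The first principal component held 49.3% of the variance, and NC replicate 3 lay farthest out on it.

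Among genes with a name, several had higher deposited values in EO without passing the test. clpP, the proteolytic subunit of the Clp protease, had 484 ± 153 TPM in NC and 1743 ± 302 in EO (SD, n = 3 each). Its log2 fold change was 1.88 ± 0.34 (SE, limma adjusted p = 0.0522), and 0.75 under median-of-ratios scaling (adjusted p = 0.303) or 0.77 with the 10 most abundant genes removed (adjusted p = 0.355). rocD, an ornithine aminotransferase, had 45.3 ± 25.1 TPM in NC and 333 ± 96.9 in EO, a log2 fold change of 2.96 ± 0.57 (SE, adjusted p = 0.0547). hemA, which encodes the first dedicated enzyme of heme synthesis, had 111 ± 70.1 and 567 ± 88.9 TPM, with 2.54 ± 0.53 (SE, adjusted p = 0.0609). Under median-of-ratios scaling rocD had 1.84 and hemA 1.41 (adjusted p = 0.137 and 0.173). spxA, a regulator of the response to thiol stress, had 5124 ± 3251 and 18957 ± 2090 TPM, with 2.19 ± 0.60 (SE, adjusted p = 0.0874). For spxA the log2 fold change was 1.06 under that scaling (adjusted p = 0.393) and 1.45 without NC replicate 3 (adjusted p = 0.0299).

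Limma called 0 of the 2171 genes tested at an adjusted p of 0.05, and so 0 at 2-fold or more. The smallest adjusted p was 0.0522, and 54 genes had one under 0.06. At an unadjusted p under 0.05 there were 590 genes, 582 higher and 8 lower in EO, where about 109 would be so by chance. The groups did not overlap for 839 genes higher in EO and 14 lower, or 39.3% of genes tested, against 10% by chance. Both chance values hold only without a common shift of all genes, and the deposited values had one, as given below. These numbers are therefore not counts of genes that respond to EO. The call of 0 rested on the settings: without NC replicate 1 there were 112 genes and without NC replicate 3 there were 97, all higher in EO. A pseudocount of 0.1 gave 120 genes, and one of 10 gave 80. These 4 settings left the common shift in, with median log2 fold changes of all genes of 1.58, 1.03, 1.67 and 0.94. Their counts are therefore not of genes that respond to EO either.

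The deposited values were higher in EO as a whole. The median log2 fold change was 1.45, and 89.4% of genes tested had a positive one. The median was 0.45 under median-of-ratios scaling and 0.55 with the 10 most abundant genes removed, and 0 genes were called under either. Fold changes of the lists below are therefore read against 1.45, the median of all genes. The p-values adjusted over a list alone test against 0, so the shift of all genes can carry a gene past that threshold.

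**Figure D2:**
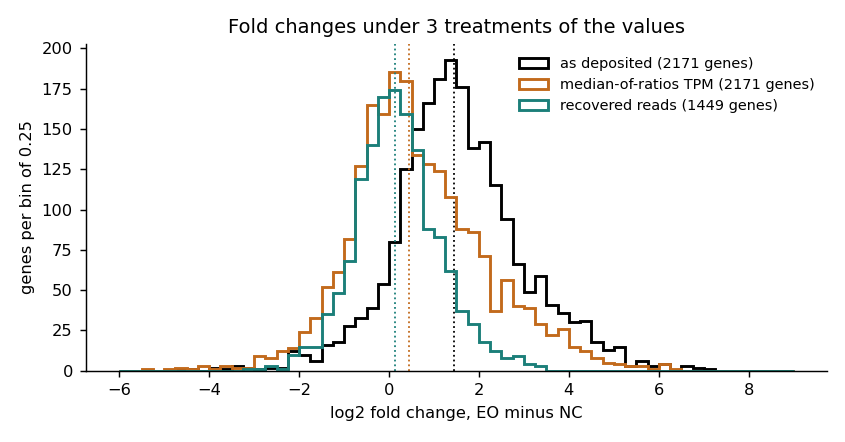
Each line counts genes in bins of 0.25 of the log2 fold change of EO over NC, for deposited values, for TPM after median-of-ratios scaling and for recovered reads. Dotted lines mark the medians of 1.45, 0.45 and 0.14.

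Of the 35 gene lists, 14 had enough measured members to be tested, and camera called 0, with a smallest adjusted p of 0.656. With an estimated correlation the smallest adjusted p = 0.923, and at an unadjusted p under 0.05 camera also called 0. No list had a member called over all genes, and the libraries' depth moved with the groups as given above. The ribosomal proteins, with 46 measured members, had a median log2 fold change of 1.97, and 44 were positive. Adjusted over the list alone, 4 passed, namely rpmA, rpmE2, rpsF and rpsL. The 2 with most reads, rpsD and rpsA, had 0.53 ± 0.36 and 1.05 ± 0.51 (SE), and both turned negative under median-of-ratios scaling. rpsD had 0.79 without NC replicate 1 and 0.34 without NC replicate 2. The aminoacyl-tRNA synthetases, which load amino acids onto tRNA, had a median of 2.37 over 14 members, all positive, and 0 passed adjusted over the list alone. In that list thrS had 18.7 ± 16.2 TPM in NC and 177 ± 5.68 in EO, while valS had a log2 fold change of 1.08 ± 0.64 (SE), which turned negative under the same scaling. Translation factors and RNA polymerase had a median of 0.88 over 11 members, 8 positive, and infA passed adjusted over the list alone. The elongation factor genes fusA and tuf had 1.297 ± 0.518 and 1.38 ± 0.47 (SE).

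The chaperones and Clp proteases had a median of 0.73 over 7 members, 5 positive. Adjusted over the list alone, 1 passed, clpP, while dnaK, the Hsp70 chaperone, had −0.19 ± 0.42 (SE), or −1.32 under median-of-ratios scaling. Peptidoglycan and teichoic acid synthesis had a median of 1.36 over 8 members, all positive, with 0 passing adjusted over the list alone. There murG had 0.86 ± 0.72, negative under median-of-ratios scaling, and murC had 1.33 ± 0.68 (SE). Fatty acid and phospholipid synthesis had 3 members with a median of 1.37, among them fabZ with 1.37 ± 0.67 and acpP with 2.93 ± 1.65 (SE). Without NC replicate 2, where it was listed at 0, acpP had 0.81. Adjusted over the list alone, 0 of those passed.

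In central metabolism, the 5 measured glycolysis genes had a median of 1.49, all positive, and 0 passed adjusted over the list alone. Of these, eno had 1.28 ± 0.49 and pgi had 2.05 ± 0.71 (SE). The 5 genes of the TCA cycle had a median of 1.19, all positive, and 3 passed adjusted over the list alone, sdhB, sucA and sucC. Under median-of-ratios scaling sucA and sucC had 0.23 and 0.38 (adjusted p = 0.797 and 0.727). The aerobic respiratory chain had a median of 1.39 over 4 members, and hemA passed adjusted over the list alone. Pyrimidine synthesis had a median of 1.39 over 6 members, with pyrG at 0.61 ± 0.93, negative under median-of-ratios scaling, and pyrH at 3.29 ± 1.43 (SE), or 1.73 without NC replicate 3, where it was listed at 0. Arginine synthesis and the arginine deiminase had a median of 2.24 over 3 members, and rocD passed adjusted over the list alone. Aromatic amino acid synthesis had a median of 1.64 over 4 members, 3 positive, with trpD at 1.79 ± 1.52 (SE), or 0.39 without NC replicate 3, where it was listed at 0. The SOS response and DNA repair had a median of 2.28 over 7 members, and recA and ruvA passed adjusted over the list alone. The alternative sugar list had a median of 1.22 over 3 members, with ulaA at 1.22 ± 0.59 and the hexose phosphate transporter gene uhpT at −0.66 ± 0.84 (SE), or −0.035 without EO replicate 2. Pyrimidine, aromatic and alternative sugar genes had 0 members passing adjusted over the list alone. The alternative test fry, which asks whether a list moves on balance one way without comparing it with other genes, called 4 lists higher in EO, with a smallest adjusted p of 0.00779. They were the aminoacyl-tRNA synthetases, the aerobic respiratory chain, the arginine list and the peptidoglycan list. The median of all genes was 1.45, so such calls can come from the shift of all genes alone. The medians of the respiratory chain and the peptidoglycan list, 1.39 and 1.36, lay below it. Camera, which compares a list with other genes, called none of them, each with an adjusted p of 0.923 at an estimated correlation.

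Another 8 lists had too few measured members for a test. Both genes of oxidative and thiol stress were positive, with a median of 2.27, and spxA passed adjusted over the list alone. Purine synthesis had a median of 2.37 over 2 genes, and purH passed adjusted over the list alone. Single measured genes gave 0.55 for fermentation and anaerobic respiration, 1.40 for ATP synthase, 1.86 for branched-chain amino acid synthesis, 1.72 for urease and 0.63 for cell division. Histidine synthesis had a median of 0.38 over 2 genes. In these last lists 0 genes passed adjusted over the list alone. The housekeeping gene tpiA, of glycolysis, had 104 ± 48.7 TPM in NC and 157 ± 48.4 in EO (SD, n = 3 each), a log2 fold change of 0.67 ± 0.56 (SE, limma adjusted p = 0.419). Its sign turned under median-of-ratios scaling. Without NC replicate 3 the log2 fold change was 0.24 for tpiA, 0.73 for eno, 1.304 for pgi, 0.71 for fusA, 0.91 for tuf, 0.65 for valS and 0.10 for murG, each over 1.5 times below the value above. The median of all genes also fell without that library, from 1.45 to 1.03, so these drops are not particular to the genes given.

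In the fit on recovered reads, added after the data were examined, spxA and rocD rose and dnaK fell with EO. The log2 fold change was 0.99 ± 0.29 for spxA (SE, limma voom adjusted p = 0.0469) and 1.72 ± 0.51 for rocD (SE, adjusted p = 0.0476). For dnaK it was −1.299 ± 0.36 (SE, adjusted p = 0.0423), with an adjusted p of 0.185 under total-read scaling. On TPM with median-of-ratios scaling dnaK had −1.32 without a call (limma adjusted p = 0.209), so its difference from the main test went with the scaling. hemA and thrS missed the threshold with 1.29 ± 0.39 and 2.25 ± 0.70 (SE, adjusted p = 0.0593 and 0.0702) and passed it under total-read scaling, with adjusted p = 0.0113 and 0.0299. SAOUHSC_02175 fell by 2.05 on the log2 scale (SE 0.26, adjusted p = 2.59e-10). It had −1.66 under total-read scaling (adjusted p = 9.12e-06) and −0.93 in the main test, which did not call it (adjusted p = 0.212). SAOUHSC_01396 fell by 2.19 (SE 0.65, adjusted p = 0.0476). The largest increases among called genes were 3.34 ± 0.80 in SAOUHSC_00285 and 2.12 ± 0.58 in SAOUHSC_02444 (SE, adjusted p = 0.0128 and 0.0351). The other most abundant genes were SAOUHSC_00825, with −0.76 ± 0.26 (SE, adjusted p = 0.104) but 0.37 in the main test (adjusted p = 0.492), and SAOUHSC_02391, with −1.46 ± 0.29 (SE, adjusted p = 0.000441). In the main test SAOUHSC_02391 had −0.31 and SAOUHSC_01396 had −1.08 (adjusted p = 0.653 and 0.347).

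On recovered reads, where the median of all genes was 0.14, the lists had other medians and some were negative. The ribosomal proteins had a median of 0.067, with 19 of 35 positive, and the TCA cycle had −0.046, with 2 of 5 positive. The chaperones and Clp proteases had −0.038, with 3 of 6 positive, and translation factors 0.087, with 5 of 8. The aminoacyl-tRNA synthetases had 1.04 (6 of 10 positive), the arginine list 1.04 (2 of 3), peptidoglycan 0.42 (5 of 7), pyrimidine synthesis 0.37 (3 of 4), glycolysis 0.25 (4 of 5), SOS and repair 0.24 (2 of 4) and alternative sugars 0.041 (2 of 3). Some lists with 1 gene measured on reads turned negative, with −1.11 for ATP synthase, −0.80 for fermentation, −0.52 for cell division and −0.036 for aromatic amino acid synthesis. Others stayed positive, with 1.29 for the aerobic respiratory chain, 0.99 for oxidative and thiol stress and 0.081 for urease. With 2 genes, purine synthesis had 0.98 and fatty acid synthesis 0.46. Adjusted over the list alone, thrS, rocD, hemA and spxA passed as higher, and dnaK and uhpT as lower. For hemA and spxA the list had 1 gene measured on reads, so that p is the unadjusted one. For uhpT the unadjusted limma voom p was 0.0061 with median-of-ratios scaling and 0.032 with total-read scaling.

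This fit called 27 of 1449 genes, 13 higher and 14 lower, of which 25 changed at least 2-fold, 11 higher and 14 lower. Total-read scaling called 28 genes, 25 higher and 3 lower, and 16 genes were shared, so the balance of higher and lower genes rested on the scaling. At an unadjusted p under 0.05 there were 198 genes, 107 higher and 91 lower. Camera on this fit called 0 of 11 lists, with a smallest adjusted p of 0.69. The count ranged from 2 without NC replicate 1 to 31 without NC replicate 3. It was 8 without EO replicate 1 and 4 without EO replicate 2. Of the genes named from this fit, only SAOUHSC_02175 passed whichever library was left out, with an adjusted p of at most 0.00326. rocD and dnaK passed only without NC replicate 3 or EO replicate 3, with adjusted p up to 0.282 and 0.269 otherwise. spxA passed only without NC replicate 2, and without NC replicate 3 its log2 fold change was 0.55. SAOUHSC_00285 had a log2 fold change of 1.19 without NC replicate 1 and passed only without an EO library, SAOUHSC_02444 only without NC replicate 3 (1.40) or EO replicate 3, and SAOUHSC_01396 only without NC replicate 3. SAOUHSC_02391 missed the threshold without NC replicate 1 or EO replicate 2 (adjusted p = 0.104 and 0.0607). Under total-read scaling SAOUHSC_01396 and SAOUHSC_02391 also missed it (adjusted p = 0.118 and 0.0539).

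**Figure D3:**
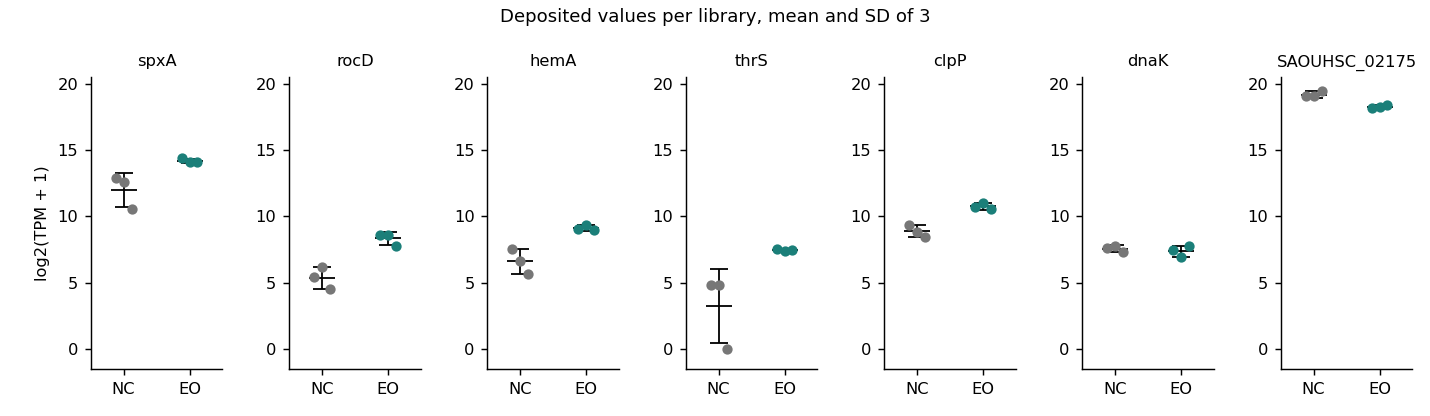
Points are deposited log2(TPM + 1) values of single libraries, and bars are the mean and SD of 3 per group, for 7 genes. thrS was listed at 0 in NC replicate 3. On this scale dnaK had a log2 fold change of −0.19, against −1.32 after median-of-ratios scaling of TPM and −1.299 on recovered reads.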

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

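The recovered-read fits, the filter at a mean of 100 TPM and the thinning were chosen after the data were examined. Genes changed by EO numbered 0 in the main test and with a mean TPM of at least 10, median-of-ratios scaling, removal of the 10 most abundant genes and robust moderation, and a median of 0 (0 to 1) over 20 thinned draws. A pseudocount of 0.1 gave 120 genes, a pseudocount of 10 gave 80, no filter 79, no trend 61, and a mean TPM of at least 100 gave 58. Recovered reads gave 27, and 28 with total scaling. For changes of at least 2-fold these numbers were 120, 80, 79, 61, 57, 25 and 28, and 0 with a test against a log2 limit of 1. Leaving out 1 library gave 0 to 112 genes, and likewise at 2-fold, with 97 and 96 without NC replicate 3. Except on recovered reads, the settings that called genes left the common shift in, with medians of all genes from 0.94 to 1.67. Those counts are therefore not of genes that respond to EO. In the main test 54 genes had an adjusted p between 0.0522 and 0.06. Gene lists stayed at 0 with camera throughout, and fry, which does not compare a list with other genes, called 4. The mean correlation within groups rose with a pseudocount of 10, to 0.785 in NC and 0.868 in EO.

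The fit on recovered reads called 27 genes, 9 with at least 10 reads, 45 with at least 100, 27 with the 6 genes of unmatched length kept, and a median of 12 (6 to 36) over 20 thinned draws. Leaving out 1 library gave 2 to 31. All 27 kept their direction wherever they were tested in these fits other than the thinned draws. No pairing of the libraries by replicate number was seen, as the deviations of same-numbered libraries correlated at 0.019, −0.11 and −0.013. Such correlations can miss a weak pairing, so one is not excluded. With the replicate number as a block, the main test called 0 genes and 0 lists, and the fit on recovered reads called 10.

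Of the named genes, some turned negative on the log2 scale under median-of-ratios scaling and with the 10 genes removed: rpsD (−0.61 and −0.59), rpsA (−0.077 and −0.057), valS (−0.027 and −0.0060), murG (−0.25 and −0.23), pyrG (−0.48 and −0.48), uvrA (−0.39 and −0.38) and tpiA (−0.45 and −0.43). SAOUHSC_00825 did so under the first (−0.77). Their main values lay below the median of all genes, which both scalings lower. Leaving out 1 library also turned signs, and the cause was not tested. The range was −0.38 to 0.039 for dnaK (highest without EO replicate 2), −0.045 to 1.21 for pyrG (lowest without EO replicate 1), −0.38 to 2.63 for argC (lowest without NC replicate 2) and −0.71 to 0.16 for SAOUHSC_02391 (highest without NC replicate 2). In the simulated data 0% of 2-fold changes were recovered in the main test and 14.6% on reads, so most changes of that size may have been missed. That simulation lacked the difference between the groups in the share of abundant genes.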

Other observations

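The tests in this part were chosen after the results they bear on had been seen, except that removal of the 10 most abundant genes was among the alternatives fixed beforehand; its limit of 0.2 was set afterwards. Of the 10 splits of the 6 libraries into 3 and 3, 10 gave as many genes as the real 0 in the main test, 10 as many at 2-fold and 10 as many gene lists, with 0 as the highest of the other splits each time. Any split reaches a count of 0, so these results say nothing about the grouping. For recovered reads, 1 of the 10 splits, the real one, reached 27 genes, and the highest of the others was 0. With 10 splits no share under 0.05 can be had.

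Deposited values were higher in EO across most genes, with a median log2 fold change of 1.45. With the 10 most abundant genes removed the median was 0.554 (0.302 without NC replicate 3), so these genes were not the whole cause. In simulated data with unequal depths and no changed gene, the log2(TPM + 1) fit gave a median of 0.18. That lies close to the limit of 0.2, so part of what was left can come from depth. With reads outside those genes thinned to one number in every library the median of all genes stayed at 1.26 (1.19 to 1.297 over 20 draws). That thinning kept the unequal share of the 10 genes, which by itself holds this median up. The outcome was thus largely set by the share, and no conclusion on depth alone is drawn from it. Both steps together gave 0.266 (0.209 to 0.337), and as low as 0.106 with a library left out. After the same steps the largest size of the median among the other 9 splits of the libraries was 0.217 (0.199 to 0.257 over draws). Whether the fixed sum of TPM and the shallower controls together account for the whole shift or leave a small rise cannot be told apart, because leaving out 1 of 6 libraries moves the median across the limit of 0.2.

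SAOUHSC_02175 and some other short genes were lower in EO, while a fall of short genes as a set was neither shown nor excluded. Of the 38 tested genes of at most 150 nt, 4 were called on recovered reads with median-of-ratios scaling. All 4 fell, and 2 of them were also called with total-read scaling. Over all 1449 genes under median-of-ratios scaling 14 were called lower, so called falls were more frequent among short genes, which was not tested. For SAOUHSC_02175 the shallow NC replicate 3 alone is argued against, because without that library its log2 fold change was −1.70. The other called short genes were not part of that test. A general loss of short transcripts was examined over all tested genes of at most 150 nt. That test first left out the called genes and was then widened to all short genes. All 38 had a median of −0.060 (SD 1.01, 95% interval from resampled genes −0.60 to 0.29), 20 lower and 18 higher. The smallest fall among the called ones, −1.26, was set by the threshold for a call. Called genes are extremes of the same fit, so a median above that value was nearly given in advance. The values show only that the typical short gene did not fall by as much as the called ones. Longer genes had a median of 0.15, and the difference gave a permutation p of 0.20. A smaller general loss can therefore be neither shown nor excluded. A loss limited to some short RNAs and an effect of EO may both remain, and neither was tested.

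Genes called on recovered reads lay beside each other more often than random genes. Among the 27, 6 had another called gene within 2 positions, against a mean of 1.16 in 10000 random draws (permutation p = 0.015). The 3 pairs, among them dnaK with a gene 2 positions away and SAOUHSC_02175 and SAOUHSC_02444 each with the adjacent gene, moved in the same direction. Shared transcripts are a candidate explanation, as is read spill between adjacent genes, which was not tested.

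Among values of 1 to 20 reads 57.1% were even, with 1137 values of 2 reads and 915 of 4, against 462 of 3 and 441 of 5, although 1 read was the most frequent number, with 1199 values.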
